A study of Mus musculus with 6 samples.

How the data were processed

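RNA from dorsal pancreata of E13.5 mouse embryos was extracted with a column kit and made into TruSeq RNA v2 libraries, sequenced on an Illumina HiSeq instrument, per the labels' protocols and the series' design text. This kit does not mark the strand of a transcript. There were 3 Bicc1 knockout and 3 wild-type libraries, with group and replicate number taken from the labels. CASAVA 1.82, Bowtie 0.12.7 and the mouse build mm9 are named in the submitters' processing notes. The gene annotation, the counting and the normalization are not given in the sources used here.

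The deposited files hold a non-negative signal per gene, 1 file per library, for 24389 Ensembl gene identifiers, and the authors' unit is not stated in the file headers. The values look like a read density normalised to length. They have a floor of 0.01, and 3244 of 3630 genes annotated with a single exon (89.4%) have 2 decimals in every library, against 229 of 18994 genes with several exons (1.21%), within a tolerance of 0.0001 of the last decimal. No counts can be derived from such values, so depth is unknown and no counting interval is given. Levels of different genes may not be on 1 scale, so comparisons were made gene by gene between libraries. Symbols were found for 22624 identifiers (92.8%) in a table of gene names and in an annotation of build GRCm38, and 1765 had none. That annotation was used only for names, the number of exons, GC content of the longest transcript, gene order and exon overlap, and none of its coordinates are given, since the build of the files is mm9.

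The deposited values were used as they are, without further scaling. Genes with a mean value of at least 1 over the 6 libraries (13911) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, group as the only term), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on this scale understate the change of low genes. An exact test of 3 against 3 values cannot give a p under 0.1, so single genes were tested only in the model across all genes. A test for counts had been planned for the case that the files held counts, and limma for normalized values.

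Before the data were examined, 25 gene lists of the embryonic pancreas, its neighbouring tissues and the pathways tied to Bicc1 were fixed, as were the tests, the alternatives given here as fixed beforehand and the rule for naming genes. Lists were tested with limma's camera (correlation between genes preset to 0.01, two-sided, adjusted over the 25 lists), again with an estimated correlation, and with fry, which tests each list alone. The count of members past the threshold is given over all genes and adjusted over the list alone. The latter is not adjusted for the number of lists and is the weaker call. The genes named are Bicc1, the genes past the threshold with groups that do not overlap (up to 12 in each direction), up to 4 members past the threshold of each list or otherwise the 2 with the lowest p, Xist and the Y-linked genes, and Neurog3, Ins1, Ins2, Gcg, Cpa1, Sox9, Pkd1, Pkd2 and Adcy6. Other genes are named with the statement that they were chosen after their values were seen, and 1 result is not reported here.

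Principal components were computed on the log2 values of the tested genes. Alternatives fixed beforehand were scaling by median ratios, totals or upper quartiles, no or a stricter filter (a value of at least 1 in 3 libraries), a pseudocount of 0.1, robust moderation, a threshold of 0.10, the replicate number as a block, and leaving out each library. Alternatives added after the data were seen were a GC correction (loess with span 0.3 per library, over the 13385 tested genes, 96.2%, with a GC content), the same with the block, the side of the first component as a term, the level of Y-linked genes as a covariate, and protein-coding genes only. The scripts were tested on simulated data for the comparison of Bicc1 KO with WT, over 13911 genes with 200 changed. Changes of 0.5 log2 units were recovered in 43.3%, of 1 unit in 74.6% and of 2 units in 95.5% of genes, with 8 false calls, and 0 of 24 unchanged lists were called. Genes were simulated as independent, unlike the libraries here. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.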

Results

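Dorsal pancreata from E13.5 mouse embryos were profiled by RNA sequencing in 3 Bicc1 knockout (KO) libraries and 3 wild-type (WT) libraries. All embryos were on a mixed background of the C57BL/6 and ICR strains. Bicc1 encodes Bicaudal C1, an RNA-binding protein, and the comparison asks how its loss alters the pancreatic mRNA profile. Each library held an expression value for the same 24389 genes. The values summed to between 674295 in WT 2 and 716255 in KO 1, and between 22619 and 22948 genes lay above the floor of 0.01. These sums are not read totals, and the depth of each library is unknown. Across genes, which are not independent replicates, Pearson's r of log2 values between pairs of libraries ranged from 0.990 to 0.998. The labels do not say whether the replicates were separate embryos or pools. In every library except WT 2, Xist (1.28 to 4.63) and Y-linked genes (mean of 4 genes, 2.34 to 5.84) were both present. Xist marks females and Y-linked genes mark males, which argues against a single embryo in each of these libraries. In WT 2 Xist was at the floor of 0.01, so there it cannot be told. The p-values measure only the spread between these samples, which may in part be technical.

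Bicc1 (ENSMUSG00000014329) was low in every KO library and high in every WT library. Its value was 3.96 in KO 1, 4.91 in KO 2 and 4.48 in KO 3, against 19.7 in WT 1, 19.5 in WT 2 and 18.2 in WT 3. The KO mean of 4.45 ± 0.479 (SD, n = 3) was 23.3% of the WT mean of 19.1 ± 0.793 (SD, n = 3), so transcript signal remained over the gene in all KO libraries. Bicc1 fell by 1.89 on the log2(value + 1) scale (SE 0.087), with an adjusted p of 0.00067 in limma with Benjamini-Hochberg adjustment. The uncharacterised gene 4930533K18Rik (ENSMUSG00000047692) also fell, from 4.97 ± 0.548 in WT to 1.49 ± 0.156 in KO (SD, n = 3 each). Its log2 change was -1.26 (SE 0.098), with an adjusted p of 0.015 in the same limma test. In the reference annotation 14.4% of its exonic bases lie within exons of Bicc1 on the opposite strand, and the library kit does not mark strand, so its value can include reads of Bicc1.

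These were the only genes of the 13911 tested that passed limma at an adjusted p of 0.05, so 2 fell and 0 rose. At an unadjusted p of 0.05, 1426 genes passed, where 695.55 would by chance. This count depended on single libraries: it was 457 without WT 1, 793 without WT 2, 852 without KO 1 and 3111 without WT 3. In 1067 genes all KO values lay above all WT values and in 1220 all lay below, together 16.4% of the genes tested, against 10% by chance. The call of 4930533K18Rik was lost without KO 1 (adjusted p 0.149), KO 3 (0.0736), WT 1 (0.150) or WT 3 (0.103), which left 1 gene, Bicc1, in each of these fits. It was lost as well when no filter on low values was applied (0.205), and over all alternatives its adjusted p ranged from 0.0074 to 0.742. Without KO 2 the count of genes at an adjusted p of 0.05 was 7, including Bicc1, 4930533K18Rik, Calcr (lower in KO), A930033H14Rik, Cma1 and Six2 (each higher). A930033H14Rik, Cma1, Six2 and Calcr were chosen after their values were seen.

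**Figure D1:**
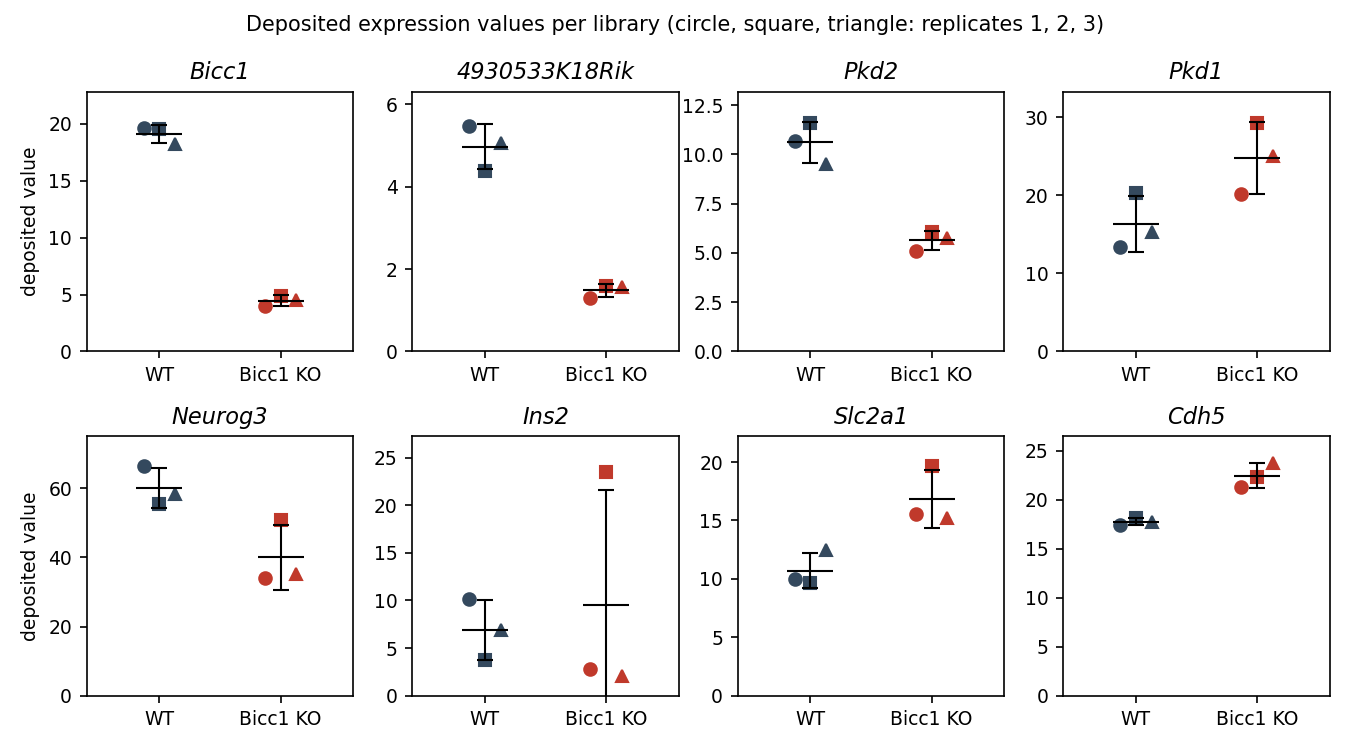
Deposited expression values (y axis, unit not stated by the submitters) of 8 genes in the 3 WT and 3 Bicc1 KO libraries, with circles, squares and triangles for replicates 1, 2 and 3. Horizontal bars are group means and whiskers are SDs. The groups are apart for Bicc1, 4930533K18Rik, Pkd2, Neurog3, Slc2a1 and Cdh5 and overlap for Pkd1 and Ins2, where KO 2 stands at 23.5.

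The largest contrast between the libraries did not separate KO from WT. On the first principal component, which held 57.3% of the variance, KO 1, KO 2 and WT 3 lay on one side and WT 1, WT 2 and KO 3 on the other. Across genes, Spearman's rho between the GC content of a gene and its deviation in a library was 0.50, 0.61 and 0.40 in KO 1, KO 2 and WT 3, and -0.56, -0.66 and -0.19 in WT 1, WT 2 and KO 3. Xist, the transcript that silences an X chromosome in females, was 3.63, 4.63 and 3.79 in the first 3 libraries and 1.28, 0.01 and 1.33 in the others. The mean of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 2.34, 4.60 and 2.35 in KO 1, KO 2 and WT 3 and 5.84, 7.92 and 5.64 in WT 1, WT 2 and KO 3. Each side holds libraries of both genotypes, so differences between KO and WT are also given within each side, as KO 1 and KO 2 against WT 3 and as KO 3 against WT 1 and WT 2. Scores on the component were still higher in KO within each side. They were 0.29 and 0.58 in KO 1 and KO 2 against 0.26 in WT 3. In KO 3 the score was -0.13, against -0.43 and -0.56 in WT 1 and WT 2. Differences within a side therefore do not fully remove the component.

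**Figure D2:**
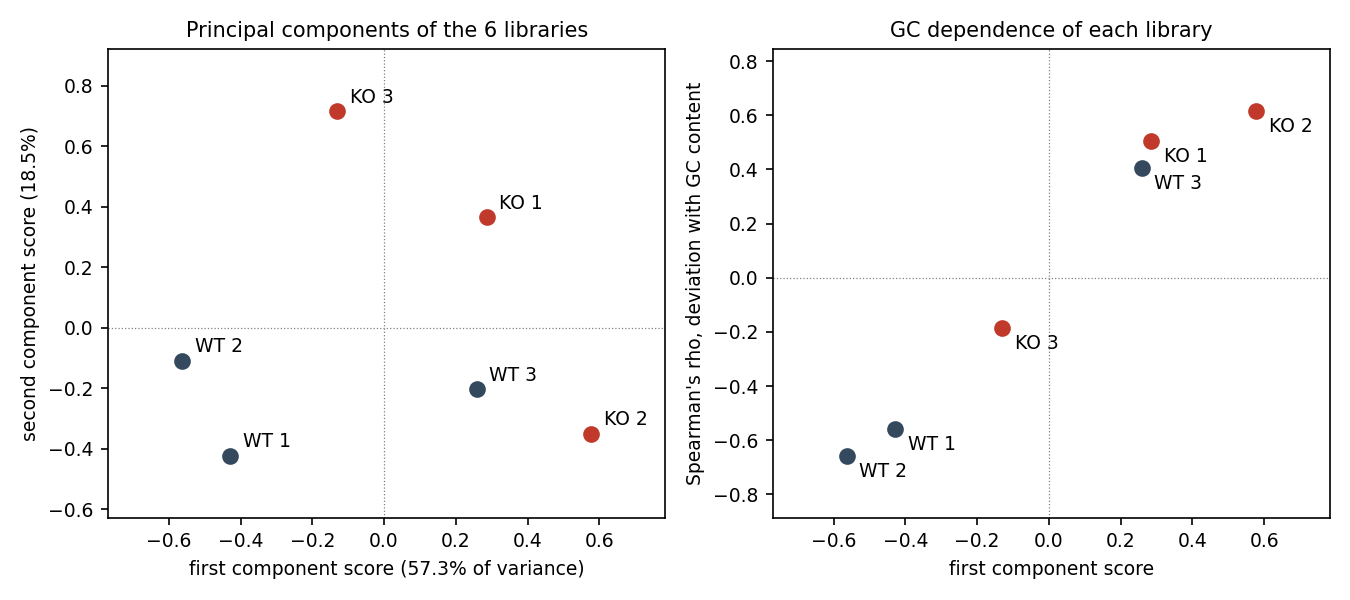
Left, scores of the 6 libraries on the first (57.3% of the variance) and second (18.5%) principal components of log2 values. Right, Spearman's rho across genes between GC content and a library's deviation from the mean (y axis), against the first component score (x axis); KO 1, KO 2 and WT 3 have positive values on both axes.

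Mutation of the polycystin genes Pkd2 and Pkd1 causes polycystic kidney disease. Pkd2 was 5.64 ± 0.484 in KO and 10.6 ± 1.04 in WT (SD, n = 3 each), 53.2% of the WT mean, and every KO value lay below every WT value. Its log2 change of -0.80 (SE 0.096) had an adjusted p of 0.13 over all genes in limma and did not pass, but adjusted over the list alone Pkd2 fell, with a p of 0.0017. It was also past the threshold over all genes after a correction for GC content, at an adjusted p of 0.047, where the alternatives ranged from 0.047 to 0.742. Pkd1 was 24.8 ± 4.58 in KO and 16.3 ± 3.58 in WT (SD, n = 3 each), with overlapping groups, an adjusted p of 0.47 over all genes and of 0.22 over the list alone. Of 37 tested genes of the primary cilium and of cystic disease, 20 had a higher and 17 a lower mean in KO. Pkd2 was the only member past the threshold adjusted over the list alone, and 0 passed over all genes in limma, with 3 at an unadjusted p of 0.05. The list as a whole did not pass limma's camera (adjusted p = 0.959), with a median log2 change of 0.013, a mean of 0.024 and a test direction towards lower. Adcy6, an adenylyl cyclase, was 11.8 ± 2.0 in KO and 10.7 ± 0.442 in WT (SD, n = 3 each), a difference within the spread that turned negative after GC correction (log2 change -0.034) and without KO 2 (-0.0067). Calcr, the calcitonin receptor gene, was chosen after its values were seen: it was 8.79 ± 1.27 in KO and 16.8 ± 0.398 in WT (SD, n = 3 each), with an adjusted p of 0.12. The alternatives ranged from 0.027, without KO 2, to 0.819.

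Of the 25 gene lists, 7 passed limma's camera with a preset correlation between genes of 0.01, 4 of them higher and 3 lower in KO. With an estimated correlation camera passed 0 lists, with 1 at an unadjusted p of 0.05. It passed 0 lists in every alternative too, with the lowest adjusted p, 0.419, without KO 2. The rotation test fry passed 0 lists for a shift in 1 direction, with 2 at an unadjusted p of 0.05, and 1 list, hypoxia and glycolysis, for change in either direction. The count of lists past camera was 14 without KO 2 and 3 without KO 3. Ranges of a list's adjusted p over alternatives are those of camera with the preset correlation.

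**Figure D3:**
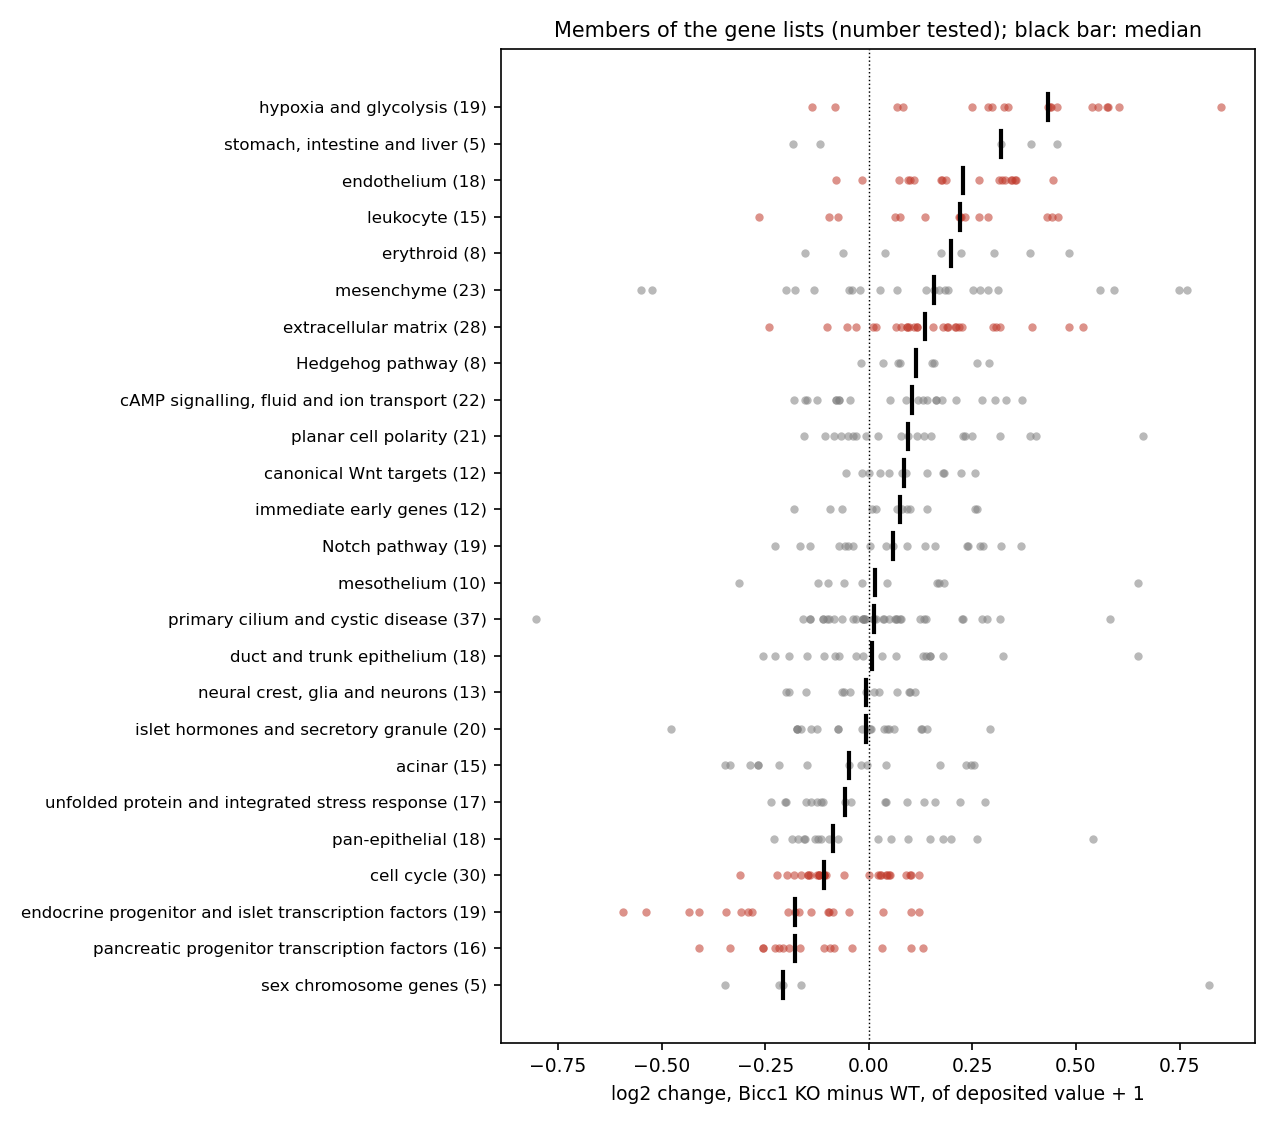
Log2 change (KO minus WT, of value + 1; x axis) of each tested member of the 25 gene lists, with the number of tested members in parentheses and a black bar at the median. Red marks the 7 lists past limma's camera with the preset correlation; hypoxia and glycolysis has the highest median, 0.43.

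Genes of the hypoxia response and of glycolysis were higher as a list in KO by camera with the preset correlation. Of 19 tested members, 17 had a higher mean in KO, and the median log2 change was 0.43. Slc2a1, which encodes a glucose transporter, was 16.8 ± 2.47 in KO and 10.7 ± 1.5 in WT (SD, n = 3 each). Pgk1, a glycolytic enzyme, was 155 ± 7.81 in KO and 123 ± 6.99 in WT. Among members chosen after their values were seen, Ldha (lactate dehydrogenase) was 159.9 ± 17.9 against 110.1 ± 14.7, and Bnip3, a mitochondrial protein induced by low oxygen, was 10.9 ± 1.28 against 7.63 ± 0.689. Limma's camera gave the list an adjusted p = 1.69e-07, and adjusted p = 0.871 with an estimated correlation. Fry gave an adjusted p of 0.249 for a shift in 1 direction and of 0.036 for change in either direction. In limma 0 members passed over all genes, 12 had an unadjusted p under 0.05, and 11 rose adjusted over the list alone. All KO values lay above all WT values in 10 members and below them in 1 (16.4% of all genes tested were apart in either direction). Within the sides of the first component the median log2 change was 0.36 for KO 1 and KO 2 against WT 3 and 0.32 for KO 3 against WT 1 and WT 2.

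Endothelial genes were also higher as a list in KO, by camera with the preset correlation only. Of 18 tested members, 16 had a higher mean in KO, with a median log2 change of 0.23. Cdh5, the cadherin of endothelial junctions, was 22.5 ± 1.25 in KO and 17.8 ± 0.359 in WT, and Cldn5, an endothelial tight junction gene, was 6.16 ± 0.444 and 4.76 ± 0.448 (SD, n = 3 each). Camera gave an adjusted p = 3.25e-05, and adjusted p = 0.871 with an estimated correlation. In limma 0 members passed over all genes, 9 had an unadjusted p under 0.05, and only Cdh5 rose adjusted over the list alone. All KO values lay above all WT values in 9 members, as they did in 1067 of all 13911 genes tested. The median was 0.15 within KO 1, KO 2 and WT 3 and 0.36 within KO 3, WT 1 and WT 2. After GC correction the median was 0.13 (adjusted p 0.0022), and the log2 change of Cldn5 went from 0.31 to 0.057, with an adjusted p over all genes of 0.47 before and 0.908 after. With the preset correlation the adjusted p ranged from 1.39e-06 to 0.0112 over the alternatives, and fry gave 0.334.

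Extracellular matrix genes were higher as a list in KO by camera with the preset correlation only. Of 28 tested members, 24 had a higher mean in KO, with a median log2 change of 0.14. Tnc (tenascin C) was 1.54 ± 0.382 in KO and 0.811 ± 0.196 in WT, and Mmp14, a membrane-bound matrix protease, was 27.0 ± 2.33 and 21.6 ± 1.15 (SD, n = 3 each). Camera gave the matrix list an adjusted p = 0.0043, and adjusted p = 0.871 with an estimated correlation. Adjusted over the list alone 0 matrix members passed limma, with 7 at an unadjusted p of 0.05. The call was lost after GC correction, with a median of 0.026 and an adjusted p of 0.260, and without KO 3 (0.198), and the alternatives ranged from 0.00012 to 0.260. Without WT 3 the median was 0.21. The median was 0.081 within KO 1, KO 2 and WT 3 and 0.21 within KO 3, WT 1 and WT 2.

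The leukocyte list was likewise higher only by camera with the preset correlation. Of 15 tested members, 12 had a higher mean in KO, with a median log2 change of 0.22. Tyrobp, an adaptor of myeloid receptors, was 4.31 ± 0.424 in KO and 2.93 ± 0.596 in WT, and the macrophage gene Cd68 was 3.34 ± 0.318 and 2.24 ± 0.540 (SD, n = 3 each). Camera gave an adjusted p = 0.012, and adjusted p = 0.875 with an estimated correlation. Adjusted over the list alone 0 members passed limma, with 5 at an unadjusted p of 0.05. The leukocyte median was 0.015 within KO 1, KO 2 and WT 3 and 0.39 within KO 3, WT 1 and WT 2. The call was lost after GC correction (median 0.054, adjusted p 0.0742), without KO 1 (0.118) and without KO 3 (0.218), in a range over alternatives from 1.61e-05 to 0.218. The neutrophil genes S100a8 and S100a9, which are not in the list and were chosen after their values were seen, were lower in all KO libraries. S100a8 was 1.28 ± 0.236 in KO and 8.19 ± 5.32 in WT, and S100a9 was 2.16 ± 0.675 and 13.1 ± 7.83 (SD, n = 3 each), each with an adjusted p of 0.47 in limma.

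Transcription factors of endocrine progenitors and islets were lower as a list in KO by camera with the preset correlation only. Of 19 tested members, 16 had a lower mean in KO, with a median log2 change of -0.18. Neurog3, which commits progenitors to the endocrine fate, was 34.0, 50.9 and 35.1 in KO 1, KO 2 and KO 3 and 66.4, 55.4 and 58.3 in WT 1, WT 2 and WT 3. Its KO mean was 66.6% of the WT mean, and the log2 change of -0.59 (SE 0.156) had an adjusted p of 0.47 in limma and did not pass. Insm1, an endocrine factor downstream of Neurog3, was 8.75 ± 2.17 in KO and 12.96 ± 1.27 in WT (SD, n = 3 each). Camera gave the list an adjusted p = 0.00039, and adjusted p = 0.875 with an estimated correlation, which was 0.53. In 4 of the 10 ways to split the 6 libraries into groups of 3, the real one counted, the median was at least as large. In limma 0 members passed, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The median was -0.039 within KO 1, KO 2 and WT 3 and -0.37 within KO 3, WT 1 and WT 2. It was -0.10 without KO 1, -0.33 without KO 2 and -0.33 after GC correction. With the preset correlation the adjusted p ranged from 6.52e-12, without KO 2, to 0.0497, without KO 3, and fry gave 0.532.

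Transcription factors of pancreatic progenitors were also lower as a list only by camera with the preset correlation. Of 16 tested members, 13 had a lower mean in KO, with a median log2 change of -0.18. Gata6 was 10.8 ± 0.664 in KO and 13.05 ± 0.367 in WT, and the Notch target Hes1 was 16.2 ± 0.941 and 19.1 ± 0.068 (SD, n = 3 each), each with all KO values below all WT values. Camera gave an adjusted p = 0.0015, and adjusted p = 0.875 with an estimated correlation. The median was at least as large in 3 of the 10 splits of the libraries, the real one counted. In limma 0 members passed, over all genes or adjusted over the list alone, with 3 at an unadjusted p of 0.05. The median was 0.023 within KO 1, KO 2 and WT 3 and -0.36 within KO 3, WT 1 and WT 2, so the lower level was not seen on the first side. The call was lost without KO 3 (median -0.085, adjusted p 0.385, the highest of the alternatives, which started at 2.82e-10). The median was -0.27 without KO 2 and -0.11 with no filter on low values.

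The cell cycle list was lower in KO by a small amount, and only by camera with the preset correlation. Of 30 tested members, 18 had a lower and 12 a higher mean in KO, with a median log2 change of -0.11. All KO values lay below all WT values in 9 members, as they did in 1220 of all 13911 genes tested. Ccne2, a cyclin of S phase entry, was 21.3 ± 1.1 in KO and 26.6 ± 1.40 in WT, and Ccna2 was 62.2 ± 0.573 and 72.8 ± 3.05 (SD, n = 3 each). Camera gave an adjusted p = 0.0071, and adjusted p = 0.871 with an estimated correlation. In limma 0 members passed, over all genes or adjusted over the list alone, with 3 at an unadjusted p of 0.05. The call was lost without KO 3 (adjusted p 0.218) and without WT 3 (0.0604), in a range over alternatives from 0.00018 to 0.218. The median was -0.028 without KO 1, -0.072 without WT 1, -0.057 after GC correction, -0.055 with the side as a term and -0.047 with Y-linked level as a covariate. It was -0.035 within KO 1, KO 2 and WT 3 and -0.10 within KO 3, WT 1 and WT 2.

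The hormone, acinar, duct and general epithelial lists did not pass camera. Ins2 was 2.84, 23.5 and 2.11 in the KO libraries and 10.1, 3.72 and 6.85 in the WT libraries, and Ins1 was 1.44, 7.20 and 1.02 against 2.67, 1.37 and 2.58, so KO 2 alone set the KO means of both insulin genes. The log2 change of Ins1 was 0.13 with KO 2 and -0.50 without it, and that of Ins2 was -0.16 and -1.11. Gcg, the glucagon gene, was 191.2 ± 39.6 in KO and 191.0 ± 42.6 in WT (SD, n = 3 each), with a log2 change of 0.0053 that turned negative when libraries were scaled by median ratios (-0.0024), totals (-0.0065) or upper quartiles (-0.0087). Cpa1, the carboxypeptidase gene of acinar and tip cells, was 266 ± 48.8 in KO and 236 ± 39.9 in WT, and Sox9, the factor of progenitors and ducts, was 48.4 ± 7.90 and 57.5 ± 2.69 (SD, n = 3 each); neither passed limma, with adjusted p of 0.65 and 0.47. Krt19, a keratin of ducts and mesothelium, was 6.32 ± 2.20 in KO and 3.70 ± 1.59 in WT, with overlapping groups.

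In the hormone and granule list 10 of 20 tested members had a higher mean in KO (camera adjusted p = 0.504), in the acinar list 5 of 15 (0.296), in the duct and trunk list 9 of 18 (0.799) and in the epithelial list 8 of 18 (0.298). Without KO 2 these lists passed camera as lower in KO, with adjusted p of 2.19e-06, 8.56e-05, 0.014 and 5.27e-05 and medians of -0.22, -0.33, -0.16 and -0.22. The epithelial list also passed as lower without WT 2 (median -0.14, adjusted p 0.025) and with the side of the first component as a term (-0.14, 0.0060). With an estimated correlation camera passed 0 lists in each of these settings. Its lowest adjusted p was 0.419 without KO 2, 0.774 without WT 2 and 0.804 with the side as a term. Over the alternatives with the preset correlation the adjusted p of these 4 lists reached 0.819, 0.888, 0.855 and 0.692. In the duct and trunk list the median (0.0081) and mean (0.038) were above 0 while the test pointed lower, and in the epithelial list the median was -0.085 and the mean 0.0038. Adjusted over the list alone 0 members of these 4 lists passed limma. At an unadjusted p of 0.05 there were 0 in the hormone list, 2 in the acinar list (Ptf1a and Reg1), 3 in the duct and trunk list and 0 in the epithelial list.

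Among signalling pathways no list passed camera. Of the planar cell polarity genes 13 of 21 tested had a higher mean in KO (adjusted p = 0.157, with alternatives from 0.0391, without WT 2, to 0.666), and adjusted over the list alone 2 rose in limma. These were Dchs1, a protocadherin, at 15.4 ± 0.429 in KO and 9.55 ± 2.60 in WT, and Wnt11 at 1.53 ± 0.138 and 0.915 ± 0.164 (SD, n = 3 each). Of the Hedgehog genes 7 of 8 had a higher mean in KO, with a median of 0.11 and an adjusted p of 0.098, which was 0.0112 without KO 2, 0.0298 without WT 2, 0.0271 with the side as a term and 0.0428 with the Y-linked covariate and reached 0.735 in other alternatives. The Hedgehog median was 0.026 with no filter on low values, 0.027 after GC correction and 0.069 without KO 3. Boc, a coreceptor, was 5.25 ± 0.711 in KO and 4.09 ± 0.217 in WT. Higher means in KO were found in 10 of 12 canonical Wnt targets (adjusted p = 0.223), 12 of 19 Notch genes (0.470) and 13 of 22 genes of cAMP signalling and fluid transport (0.504). Axin2, a Wnt target, was 6.03 ± 1.01 in KO and 4.86 ± 0.375 in WT, and the water channel gene Aqp1 was 7.96 ± 0.649 and 6.43 ± 0.852 (SD, n = 3 each). Adjusted over the list alone 0 members of the Hedgehog, Wnt, Notch and cAMP lists passed limma, with 2, 0, 4 and 2 members at an unadjusted p of 0.05.

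The stress lists did not pass either. In the unfolded protein and integrated stress response list 10 of 17 tested members had a lower mean in KO (camera adjusted p = 0.298, with alternatives from 0.0019, without KO 2, to 0.952), and among 12 immediate early genes 9 had a higher mean (0.611). Hspa5, the chaperone of the endoplasmic reticulum, was 386 ± 37.2 in KO and 453 ± 28.4 in WT (SD, n = 3 each). Adjusted over the list alone 0 members of either list passed limma, with 1 in each at an unadjusted p of 0.05.

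Markers of other cell types and tissues gave mixed results. Of 23 tested mesenchymal genes 15 had a higher mean in KO (camera adjusted p = 0.223, with alternatives from 0.0067, without KO 2, to 0.684), and adjusted over the list alone 1 rose and 1 fell in limma, with 7 at an unadjusted p of 0.05. Nkx3-2, a factor of splanchnic mesenchyme, was 2.29 ± 0.271 in KO and 0.981 ± 0.431 in WT, and Dcn (decorin) was 45.0 ± 6.52 and 66.2 ± 8.69 (SD, n = 3 each). Of 5 tested genes of stomach, intestine and liver 3 had a higher mean in KO (0.604), and the transferrin gene Trf rose adjusted over the list alone, at 92.8 ± 4.80 in KO and 74.2 ± 3.34 in WT. Camera gave adjusted p of 0.925 for 10 mesothelial genes, 0.504 for 13 genes of neural crest, glia and neurons, 0.662 for 8 erythroid genes and 0.662 for 5 sex chromosome genes. The mesothelial median was 0.014 and mean 0.060 while the test pointed lower. Adjusted over the list alone 0 members of these last 4 lists passed limma, with 1, 0, 0 and 0 at an unadjusted p of 0.05. The haemoglobin gene Hba-a2 ranged from 535 to 1054 in KO and from 377 to 955 in WT.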

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

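The GC correction, the side and Y-linked terms and the restriction to protein-coding genes were chosen after the results were seen. The planned tests for counts, with their scaling factors, weights and filters, were not run because the files hold no counts, and for the same reason it is unknown what depth limits. Bicc1 was lower in KO under all 20 alternatives run and past the threshold in 19, with adjusted p from 0.00019 to 0.088. Apart from leaving out libraries, 998 log2 changes of named genes kept their direction and side of the threshold, 12 reversed, 4 came past the threshold and 5 were lost. For lists it was 321, 20, 5 and 4. With a library left out it was 415, 15, 4 and 4 for genes and 113, 22, 9 and 6 for lists. The median change of all genes stayed between -0.0089 and 0.031. The count of 2 genes became 1 with no filter on low values (24389 genes tested), 4 after GC correction (Pkd2 and A930033H14Rik added), 1 with Y-linked level as a covariate, and 1 among protein-coding genes, where 4930533K18Rik is not tested. It ranged from 1 to 7 when a library was left out (7 without KO 2). The count of 7 lists became 0 with an estimated correlation (lowest adjusted p 0.871) and 0 with fry (0.249), and ranged from 3 (without KO 3) to 14 (without KO 2). Where no construction is named, the cause was not tested.

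Libraries with the same replicate number did not deviate together (correlations of -0.22, -0.40 and -0.64), and none correlated best with its own number. The first component dominates these deviations, so a smaller effect shared by a number could be hidden, and pairing is not excluded. With the replicate block the count of genes was 0 in limma, with 656 at an unadjusted p of 0.05 and an adjusted p of 0.088 for Bicc1. After GC correction with the replicate block it was 1. The list counts were 7 and 6, with the epithelial list past the threshold as lower in the latter (median -0.13, adjusted p 0.032).

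These values reversed, all without having passed over all genes. After GC correction, with or without the replicate block, log2 changes were -0.034 for Adcy6, and list medians were -0.092 for duct and trunk, -0.014 for cAMP signalling, -0.033 for Notch, -0.069 for immediate early genes and -0.071 for mesothelium. With the side as a term they were 0.14 for Ddx3y, 0.11 for Kdm5d, 0.083 for Uty, -0.11 for Ins1, -0.065 for duct and trunk and 0.11 for sex chromosome genes. With the Y-linked covariate they were 0.054 for Ddx3y, 0.054 for Kdm5d, 0.023 for Uty, 0.0087 for acinar, -0.0073 for mesothelium and 0.054 for sex chromosome genes. With no filter, medians were 0.0040 for hormones, 0.015 for neural crest and -0.011 for stomach, intestine and liver. Gcg was -0.0024, -0.0065 and -0.0087 under scaling by median ratios, totals and upper quartiles, and duct and trunk -0.0026 and -0.0051 under the latter 2. Leaving out a library gave ranges from -0.0067 to 0.18 for Adcy6, -0.66 to 0.15 for Ddx3y, -0.18 to 0.18 for Gcg, -0.50 to 0.51 for Ins1, -1.11 to 0.38 for Ins2, -0.53 to 0.12 for Kdm5d and -0.60 to 0.13 for Uty. For list medians they were -0.22 to 0.11 for hormones, -0.33 to 0.14 for acinar, -0.16 to 0.093 for duct and trunk, -0.22 to 0.046 for epithelial, -0.011 to 0.054 for cilium, -0.17 to 0.031 for unfolded protein response, -0.016 to 0.11 for immediate early genes, -0.10 to 0.12 for mesothelium, -0.055 to 0.076 for neural crest, -0.017 to 0.30 for erythroid and -0.60 to 0.12 for sex chromosome genes. The cause was not tested.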

Other observations

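The genes named in the first 2 paragraphs (apart from Nkx3-2), the tests after GC correction or with the side as a term, and the count of neighbouring genes without the 2 leading genes were chosen after the results were seen. No enrichment was tested for these genes as groups, so they stand as single values. Of the 9 stomach and spleen factors looked at, 4 also belong to lists fixed beforehand, which were tested above. S100a8, a neutrophil gene, was 1.33, 1.02 and 1.48 in KO 1, KO 2 and KO 3, against 3.86, 6.58 and 14.1 in WT 1, WT 2 and WT 3. Its partner S100a9 was 2.16 ± 0.675 in KO and 13.1 ± 7.83 in WT, Ngp (neutrophilic granule protein) was 0.396 ± 0.079 and 3.10 ± 1.91, and the stefin gene BC100530 was 0.514 ± 0.132 and 3.58 ± 2.52 (SD, n = 3 each). Of other neutrophil and stefin genes looked at, Camp, Ltf, Stfa1, Stfa2, Stfa3 and Chil3 also had all KO values below all WT values. Their values were low, with KO means from 0.066 (Stfa2) to 0.328 (Chil3) and WT means from 0.516 (Ltf) to 2.39 (Stfa1). Lcn2, Mmp8 and Retnlg had overlapping groups. S100a8, S100a9, Ngp and BC100530 had an adjusted p of 0.47 in limma and did not pass, and the WT libraries differed among themselves, with WT 3 highest for each.

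Cma1, a mast cell chymase, was 3.27, 1.17 and 2.89 in KO 1, KO 2 and KO 3 and 0.416, 0.287 and 0.466 in WT 1, WT 2 and WT 3, with an adjusted p of 0.47 in limma, and alternatives from 0.014, without KO 2, to 0.908. Of other mast cell genes looked at, Mcpt4, Mcpt2 and Tpsb2 also had all KO values above all WT values, at means under 0.4. Cpa3, Ms4a2 and Fcer1a had overlapping groups, as did Kit, which mast cells share with other cells, at 6.94 ± 0.342 in KO and 7.08 ± 0.254 in WT (SD, n = 3 each). Six2, a transcription factor of stomach mesenchyme, was 4.50, 1.35 and 3.14 in the KO libraries and 0.122, 0.119 and 0.387 in the WT libraries, with an adjusted p of 0.47, and alternatives from 0.028, without KO 2, to 0.908. Barx1 was 3.69 ± 1.17 in KO and 1.78 ± 0.815 in WT, and the spleen factor Tlx1 was 8.71 in KO 3 but 3.15 and 2.41 in KO 1 and KO 2, against 2.43 ± 0.329 in WT (SD, n = 3 for groups). Of other factors looked at, Nkx3-2 and Nkx2-5 also had all KO values above all WT values. Hoxa5, Osr1, Msx1 and Pitx1 had overlapping groups, with adjusted p of 0.998 for Hoxa5 and 0.828 for Osr1.

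Ins2, Chgb and Neurog3 were higher in KO 2 than in KO 1 and KO 3. Ins2 was 23.5 there against 2.84 and 2.11, Chgb, a secretory granule gene, was 183 against 76.5 and 97.2, and Neurog3 was 50.9 against 34.0 and 35.1. Gcg was 226 in KO 2 against 148 in KO 1 and 199 in KO 3. In WT, Ins2 ranged from 3.72 to 10.1, Chgb from 139.7 to 181.8, Neurog3 from 55.4 to 66.4 and Gcg from 144.7 to 228.5.

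KO 1, KO 2 and WT 3 stood apart from WT 1, WT 2 and KO 3 on the first component. The same split held 41.7% of the variance after GC correction, down from 57.3%, so part of it went with GC. The correction used the longest transcript in an annotation of another build and may be incomplete. What remained therefore cannot exclude GC content as the whole cause. The split was not confined to X- and Y-linked genes or ribosomal genes. Its share was 57.6% over 13233 genes without X- and Y-linked genes and 54.4% over 11476 protein-coding genes without ribosomal protein genes. Most of the 13911 tested genes remained in both sets, so a large fall was unlikely from the start and these shares weigh little. A batch of library preparation, a different sex makeup acting on autosomal genes, or a difference in RNA quality stay open as untested, and the labels give no batch. No biological explanation was tested, since the split crosses the genotypes.

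The higher hypoxia and glycolysis genes in KO were tested against technical sources. GC bias as the whole source is argued against only as far as the correction removed it. The list kept a median log2 change of 0.31 after GC correction (0.43 before). Camera with the preset correlation gave it an adjusted p of 1.73e-10 there. With an estimated correlation camera passed 0 lists after GC correction (lowest adjusted p 0.494), so that p carries little weight. The lower of the within-side medians was 0.32, but KO libraries also scored higher on the first component within each side. That comparison therefore cannot exclude the split of the libraries. As the whole source the split is argued against, since the median was 0.43 for KO against WT. The highest absolute median of the other splits, which include the one along the component, was 0.23. Reads shared with pseudogenes named after a member are argued against as the whole source. The 16 members without a pseudogene named after them had a median of 0.38, with 87.5% higher in KO. Pseudogenes under other names were not searched, so reads shared with those stay open. The time between dissection and freezing was not tested, so the source stays open, and the list did not pass with an estimated correlation (adjusted p = 0.871).

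Besides Bicc1, the lowest adjusted p were those of 4930533K18Rik, the tested gene next to Bicc1, and A930033H14Rik, 7 tested genes away, at 1.88 ± 0.202 in KO and 0.492 ± 0.102 in WT (SD, n = 3 each; adjusted p 0.057 in limma). For 4930533K18Rik a candidate source is reads of Bicc1, since 14.4% of its exonic bases (349 of 2427) lie within exons of Bicc1. For A930033H14Rik this is argued against, with 0% (0 of 2969 bases) and a change in the other direction. A stretch of another strain linked to the targeted allele could alter neighbouring genes: 18 of the 100 nearest tested genes had an unadjusted p under 0.05, against 10.2% of the other 13810 (Fisher's exact p = 0.0186, two-sided; odds ratio 1.94, 95% interval 1.09 to 3.26). Without these 2 genes it was 16 of 98 (exact p = 0.0628), so linked variation stays open, and 3 of 124 stretches of 100 genes had at least 18.

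Of the 10 ways to split the 6 libraries into groups of 3, 2 gave at least as many genes past the threshold in limma, and 10 splits are too few for a share under 0.05. The real split gave 2 genes and the highest of the others 1065, for KO 1, KO 2 and WT 3 against the other libraries, which points to a structure of the samples; with the side as a term the comparison of KO with WT gave 2 genes. For lists, 6 of the 10 splits gave at least as many, with 7 in the real split and 14 in the highest of the others. Of the 7 lists past camera, hypoxia and glycolysis, endothelium and cell cycle had their largest median in the real split. So did lists that did not pass camera: cAMP signalling, Hedgehog, mesenchyme, and stomach, intestine and liver. That rank is therefore not particular to the lists past camera. With the real split counted, the median was at least as large in 2 of 10 splits for the matrix and leukocyte lists, 3 for progenitor factors and 4 for endocrine factors.

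Some of the highest values belong to genes that are not known for such levels. Rcc1, a chromatin-bound exchange factor, had a mean of 8000 over the 6 libraries and Wdr77 of 7738, close to the 7713 of Eef1a1, the translation elongation factor. The mean was 7354 for Rae1 and 6137 for Wac. Apart from these values, levels of different genes are not compared in the text.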
